A study of Oryza sativa with 6 samples.

How the data were processed

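RNA from roots of rice (Oryza sativa) was measured on 6 one-colour Agilent arrays, 3 from control roots and 3 from roots treated with the rhizobacterium Pseudomonas putida RF3. Group and replicate number were taken from the sample labels, which call the replicates biological without saying whether each came from a separate plant or culture, so p-values measure the spread between these samples. The labels give 48 h for the treated samples and no time for the controls. According to the labels' protocols, seedlings were germinated on MS medium, kept in a hydroponic set-up with Hoagland's solution, and total RNA was converted with an oligo-dT primer to cRNA carrying the dye Cy3. By the file headers the arrays were on 2 slides: slide 1 held replicates 2 and 3 of both groups (4 arrays) and slide 2 held replicate 1 of both groups (2 arrays).

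Each scanner file holds the intensity of 45220 spots, of which 43803 are not control spots. Per the file headers, the authors' processed intensity was background-subtracted and detrended within the array by Agilent Feature Extraction 11.5.1.1, and nothing was done to make arrays comparable. The deposited value table holds log2 values. Set against the scanner files, each of its columns was log2 of the processed signal minus a constant close to that array's 75th percentile, with offsets between -0.0199 and -0.0148, and the genes were not centred. Control replicate 1 was an exception for dim probes: 3153 of 40695 probes (7.75%), all with a processed signal below 1, had a single value in its column, up to 0.139 above the signal minus that constant. In the other 5 columns no probe differed by more than 5.15e-05. Its column medians were -3.26, -3.09 and -3.15 for control replicates 1 to 3 and -3.24, -3.09 and -3.13 for treated replicates 1 to 3. The normalisation steps the authors took for that table are not given in the sources used here.

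Control spots were left out, spots marked as outliers by the scanner software were set to missing, and spots of the same probe were averaged, which left 42249 probes for 37141 loci. The processed signal was log2-transformed and each array's 75th percentile was subtracted. A probe was kept if it was well above background on all 3 arrays of at least 1 group and had at least 2 values per group. Each locus was represented by its probe with the highest mean signal, so that 22665 genes were tested. Of these, 21296 were well above background on all 6 arrays, 3064 had several probes that passed, and 5379 rested on a probe that the array's maker marked as cross-hybridising. Among all 9087 probes marked in this way, the next match given was another locus for 3547. Genes carry the locus identifiers and descriptions of the array's design (genome build IRGSP5). Of these loci, 1 matched the reference table of gene names, so names come from the descriptions alone. Probe coordinates are not reported here. A probe at background on all arrays of a group has only a bound there, and the difference is then given as "at least N-fold": the bright group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal.

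Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided), without a block, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Gene lists were compared with limma's camera, with the inter-gene correlation preset at 0.01, over the 22624 genes with a value on all 6 arrays, and adjusted over the 27 lists. Camera with a correlation estimated per list and fry were run beside it. Fry tests whether the genes of a list move one way on balance and does not compare the list with other genes. The design, the alternatives, the rule for named genes and the lists were fixed before the data were examined. The lists cover pathogenesis-related proteins, diterpenoid phytoalexin biosynthesis, phenylpropanoid and flavonoid biosynthesis, class III peroxidases, glutathione and ROS scavenging, WRKY factors, ethylene, jasmonate, salicylate, auxin, abscisic acid and dehydration, gibberellin and cytokinin, receptor-like kinases, NLR resistance proteins, nitrogen, phosphate, iron and metals, cell wall loosening, aquaporins, organic solute transporters, heat shock proteins, and ribosomal proteins. Markers of shoot tissue, dividing cells, xylem, the endodermis and exodermis, and root hairs made up the rest. Descriptions in the files lack spaces, so the fixed patterns were adapted, and words that then matched by accident were excluded from 13 lists before any result was seen. Of the genes tested, 5 belong to more than 1 list. The named genes are the 12 with the largest rise and the 12 with the largest fall among genes past the threshold with no overlap between groups and a name. Where fewer passed, genes of the smallest p were added under the same conditions, and clone names did not count as names. Up to 4 members of the smallest p are named per list.

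Equal replicate numbers were checked for pairing. Across genes, the deviations of control and treated arrays from their group means correlated at r = 0.707 for replicate 1, 0.614 for replicate 2 and 0.272 for replicate 3, so the numbers pair the samples by the criterion of 0.1 for every pair. Within slide 1 the unmatched arrays correlated as well as replicate 3 did (0.285 for control 3 with treated 2 and 0.285 for control 2 with treated 3), so for replicate 3 the correlation does not tell the shared number from the shared slide. The other unmatched pairs lay between -0.639 and -0.375. The pairing comes from the shared number in the labels and these correlations, and replicate 1 of both groups also shares a slide. Genes are not independent replicates. The fit with the replicate number as a block and the fit with the slide as a block were therefore computed beside each result. The other alternatives were normexp background correction (offset 50), quantile normalisation, median centring, no filter on detection, detection on all 6 arrays, the mean of a gene's probes, each probe alone, slide 1 alone, an intensity trend with robust variance, array weights, an ordinary t statistic, the deposited value table and each array left out in turn. Normexp with this offset adds a constant to every signal, so fold changes of dim probes come out smaller with it, also those given here as bounds. Added after the data were seen were specific probes alone, both blocks with a trend and robust variance, removal of each array's trend on probe GC content, both blocks with an estimated correlation, and the lists within slide 1.

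The procedure was tested on simulated data for this comparison, with 22624 genes drawn independently of each other. Their means came from these arrays, and their spread was limma's moderated variance, which differs less between genes than the measured variance. The data simulated without a block held no slide or pair structure. Recovery on the real arrays may therefore be lower than in the simulation. At a log2 change of 1, limma without a block recovered 20 of 50 raised genes, and at -1 it recovered 17 of 50 lowered genes. At changes of 3 and -3 it recovered 47 and 48 of 50, and 7 of the 22424 unchanged genes were called. A list shifted by 0.5 had an adjusted p of 2.92e-16, or 0.0216 with an estimated correlation, and 0 of 26 unchanged lists were called. With the replicate block, 36 and 37 of 50 genes were recovered at changes of 1 and -1, 50 and 49 at 3 and -3, and 18 unchanged genes were called. The shifted list then had an adjusted p of 6.58e-47, but 0.069 with an estimated correlation, so that a true shift of this size was missed in that setting, and 0 of 26 unchanged lists were called. In the real lists the estimated correlations between genes ranged from -0.117 to 0.928. The absence of false calls among independent genes therefore does not show how camera with a preset correlation of 0.01 behaves on correlated lists. The number of arrays limits the precision. Figures were drawn with matplotlib.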

Results

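Transcript levels were compared between roots of rice plantlets kept in hydroponic solution and roots of plantlets exposed to Pseudomonas putida RF3, a bacterium that lives around roots and promotes plant growth. The question put by the series is how the root transcriptome responds to this bacterium. Each group had 3 arrays. The share of spots well above background was 70.6%, 64.0% and 63.9% in control replicates 1 to 3 and 69.9%, 65.1% and 60.7% in treated replicates 1 to 3, and between 24 and 49 spots per array were saturated. The first principal component held 61.8% of the variance and set control replicate 1 (score -87.1) and treated replicate 1 (-44.4), which shared slide 2, apart from the 4 arrays of slide 1. The second component held 14.5%, and all 3 treated arrays (24.7, 13.0 and 27.9) lay above the 3 controls (-2.21, -40.9 and -22.5). Treated arrays also lay above the control of the same number on the first component, by 42.7, 37.4 and 40.5 for replicates 1 to 3, so the first component does not belong to the slide alone.

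**Figure D1:**
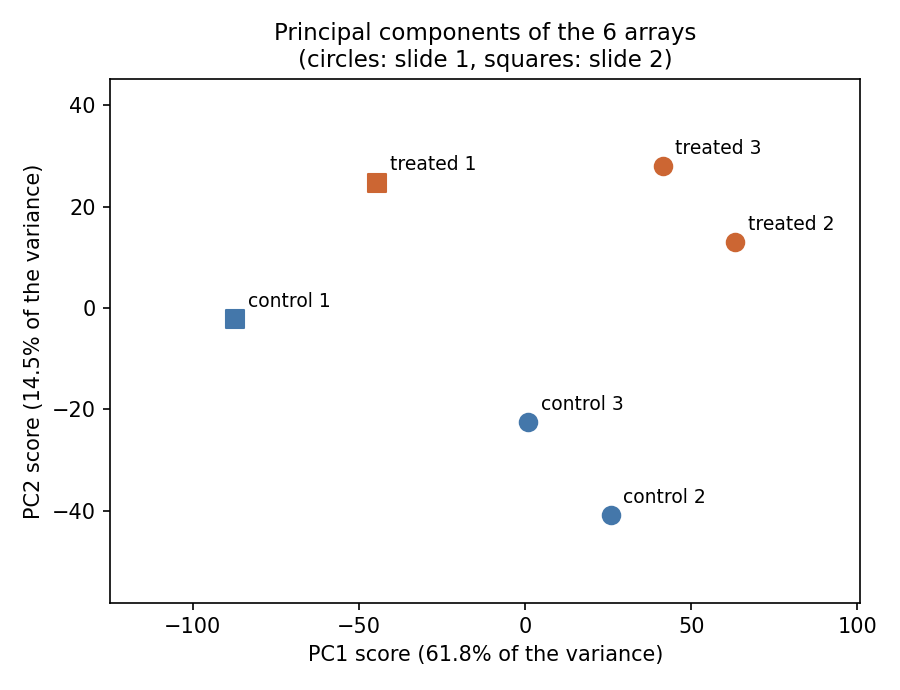
Scores of the 6 arrays on the first (horizontal, 61.8% of the variance) and second (vertical, 14.5%) principal components of the normalised log2 signal; blue points are control arrays, orange points treated arrays, circles slide 1 and squares slide 2. The first component separates the slides and is higher in the treated array of each replicate (by 37.4 to 42.7), and the second has the treated arrays at 13.0 or higher and the controls at -2.21 or lower.

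The genes that separated the groups most clearly included a chitinase, fatty acid desaturases, a sesquiterpene synthase and a gene of tryptophan biosynthesis. A chitinase (Os10g0416500), an enzyme that cleaves fungal cell walls, was 10.8-fold higher (log2 fold change 3.43 ± 0.53, SE). A delta-12 oleic acid desaturase (FAD2, Os07g0417200) and its neighbouring omega-6 desaturase (Os07g0416900), enzymes that make polyunsaturated fatty acids, were 7.56-fold and 4.58-fold higher. A sesquiterpene synthase (Os08g0168400), of the family that makes volatile terpenes, had a log2 fold change of 3.32, with its probe well above background on 1 of 3 control arrays, and an indole-3-glycerol phosphate synthase (Os09g0255400), an enzyme of tryptophan biosynthesis, differed by 2.36 ± 0.34 on the log2 scale. With normexp the log2 fold changes of Os08g0168400 and Os09g0255400 were 0.54 and 1.17. The rule for named genes required each of them to be higher on all 3 treated arrays than on any control array. Such a lack of overlap, in either direction, was seen for 11.7% of all genes, where chance gives 10% for independent arrays. None of the genes above passed limma's threshold (adjusted p = 0.584 for each).

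Smaller differences with little spread were seen for 2 PR-1 proteins, secreted defence markers. Os10g0191300 (PR-1a), already among the brighter genes, went from 5.79 ± 0.18 in controls to 6.94 ± 0.21 in treated roots (SD, n = 3, log2 relative to the array's 75th percentile). PR1c (Os02g0472500, on a cross-hybridising probe whose next match is Os10g0191300) had a log2 fold change of 1.47. Other named genes with higher signal were a UDP-glycosyltransferase (Os07g0503900, 1.37), a raffinose synthase (Os08g0495800, 0.94), an isocitrate lyase of the glyoxylate cycle (Os07g0529000, 1.24) and an esterase or lipase family gene (Os01g0317500, 3.69). The raffinose synthase and esterase probes were marked as cross-hybridising, the first with its next match in the same locus. The esterase was well above background on 2 of 3 control arrays. A TIGR01570 family gene (Os08g0476600) was not well above background on any control array and was at least 4.10-fold higher in treated roots. With normexp the log2 fold changes were 0.46 for Os08g0476600, 0.92 for Os02g0472500, 0.41 for Os07g0503900 and 1.61 for Os01g0317500. The adjusted p was 0.584 for each of these genes as well.

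Genes with lower signal in treated roots differed less. The largest of the 12 named differences was that of a nodulin-like gene (Os05g0493800), with a log2 fold change of -2.09 ± 0.39 (SE), followed by a nonspecific lipid-transfer protein (Os05g0550600, -1.45), a thioredoxin-fold protein (Os05g0198200, -1.16) and a protein phosphatase 2C (Os05g0537400, -1.07). Transcription factors among them were the homeodomain-leucine zipper gene HOX25 (Os09g0379600, -0.91) and a NAM-domain gene (Os09g0509100, -0.74). A glycerol-3-phosphate acyltransferase similar to GPAT5 (Os05g0457800), an enzyme class that makes suberin precursors, differed by -0.75, and a different chitinase (Os01g0303100) by -0.80. The remaining named genes were a protein kinase (Os02g0807200, -0.84), a glycosyltransferase (Os01g0142300, -0.85), an Avr9/Cf-9 rapidly elicited gene (Os06g0142650, -0.71) and an ATPase-like gene (Os12g0120200, -0.77). The probes of Os01g0142300 and Os06g0142650 were marked as cross-hybridising, the first with its next match in the same locus. HOX25 and Os06g0142650 were well above background on 1 of 3 treated arrays and Os12g0120200 on 2. With normexp the log2 fold changes were -1.10 for Os05g0493800, -0.55 for Os05g0537400, -0.14 for HOX25 (Os09g0379600), -0.41 for Os01g0303100, -0.51 for Os02g0807200, -0.52 for Os01g0142300, -0.12 for Os06g0142650 and -0.25 for Os12g0120200. None passed the threshold (limma adjusted p = 0.584 for each).

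**Figure D2:**
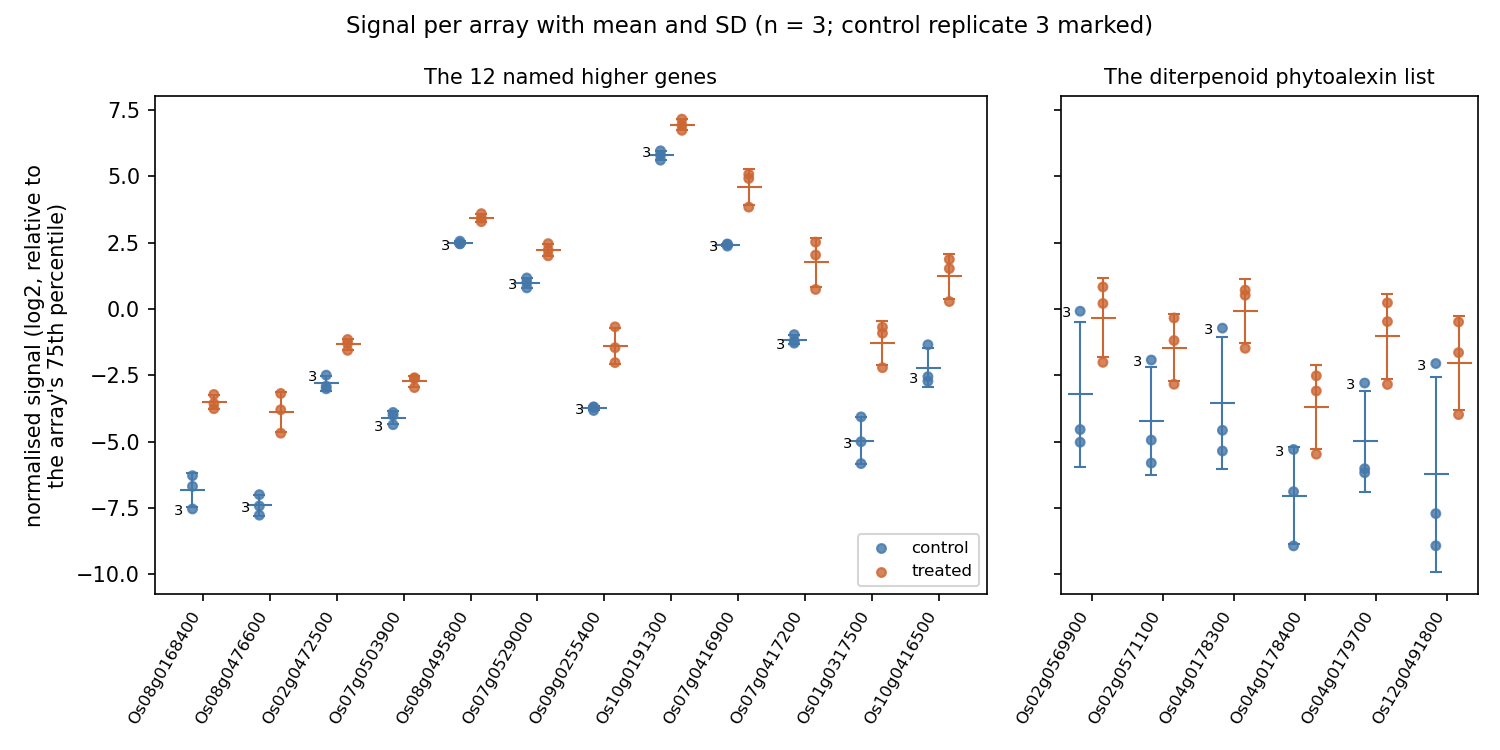
Normalised signal (log2, relative to each array's 75th percentile) of the 12 named higher genes and the 6 tested genes of the diterpenoid phytoalexin list. Points are arrays, bars are mean and SD (n = 3), blue is control and orange treated, and control replicate 3 is marked 3. For Os07g0417200 (FAD2) control replicate 3 lies at -1.29 beside the other controls, whereas for Os04g0178300 it lies at -0.73, nearer to the treated arrays than to controls at -4.58 and -5.36.

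Over all 22665 genes tested, limma called 0 genes higher and 0 lower. At an unadjusted p under 0.05 there were 1436 genes, 613 higher and 823 lower, of which 195 and 83 differed by at least 2-fold. The groups did not overlap for 2648 genes (11.7%), where chance gives 10% for independent arrays, a value that does not allow for the pairing. The ordinary t statistic, a trend with robust variance and array weights also called 0 genes, with 1478, 1377 and 3897 at an unadjusted p under 0.05. With the replicate number as a block limma called 0 genes (smallest adjusted p = 0.116) but 3851 were below an unadjusted p of 0.05, with the balance turned to 2062 higher and 1789 lower, and with the slide as a block 0 genes (0.0616) and 3314, 1639 higher and 1675 lower. Without control replicate 3 the unadjusted count was 943, and without treated replicate 1, 2 or 3 it was 2819, 926 and 922.

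Within slide 1, which held 2 arrays of each group, limma called 10 genes higher and 0 lower. They were the chitinase Os10g0416500, both desaturases, the germin-like protein 8-6 gene (Os08g0189500), a thaumatin-like protein gene (Os12g0629600), the glucanase genes Os01g0940700 and Os01g0944500, a leucine-rich repeat extracellular glycoprotein gene (Os11g0514500), a GRAS transcription factor gene (Os05g0485400) and an unnamed gene (Os01g0937800, not well above background on any control array). Chitinases, thaumatin-like proteins and glucanases are classical pathogenesis-related proteins. The chitinase was 4.33 log2 units higher within slide 1 (adjusted p = 0.0222) and 1.63 in the pair on slide 2. The glucanase Os01g0940700 was 4.62 higher within slide 1 and 0.12 on slide 2. For the glucanase Os01g0944500 the differences were 3.55 and -0.02. The next match of its probe is Os01g0940700, so these 2 genes are not separate evidence. The difference between the slides was not tested, and the probes of Os12g0629600, Os01g0940700, Os01g0944500 and Os01g0937800 were marked as cross-hybridising. For Os01g0940700 the next match was the same locus.

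With the replicate block, an intensity trend and robust variance, chosen after the data were seen, limma called 21 genes higher and 3 lower. The higher genes included PR-1 genes (Os10g0191300 and Os07g0128800), a class III chitinase (Os11g0702100), the germin-like gene Os08g0190100, a blight-associated p12 gene (Os06g0688300), the sesquiterpene synthase and the raffinose synthase. An ACC synthase (Os01g0192900) and an ACC oxidase (Os05g0149400), which carry out the last steps of ethylene biosynthesis, were also among them, with log2 fold changes of 3.73 and 2.08. Os01g0192900 was well above background on 1 of 3 control arrays, and its log2 fold change was 0.77 with normexp. The 3 lower genes were HOX22 (Os04g0541700, -1.18), an LEA-like gene (Os05g0542500, -0.87) and a conserved gene without a name (Os08g0539200).

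Pathogenesis-related proteins rose as a list. Of 101 members tested, 71 had a positive log2 fold change, with a median of 0.30 (camera adjusted p = 3.71e-05). With an estimated correlation the adjusted p was 0.456. At an unadjusted p under 0.05, 17 members were higher and 3 lower; 0 passed over all genes, and 3 higher and 1 lower passed when adjusted over the list alone. Those were PR1c, PR-1a and the chitinase Os10g0416500 on the higher side and the chitinase Os01g0303100 on the lower side. With the replicate block, 20 higher and 3 lower members passed when adjusted over the list alone. The list's median was 0.30 within slide 1 and 0.24 on slide 2, and its adjusted p was 4.16e-05 with the slide as a block and 1.12e-06 within slide 1. Without control replicate 1 the median was 0.11, without treated replicate 1 it was 0.52, without treated replicate 2 it was 0.17 and with normexp it was 0.19. The list's median difference of slide 2 from slide 1 was -0.35.

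Genes of diterpenoid phytoalexin biosynthesis had the largest list difference. The pathway makes momilactones and phytocassanes, antimicrobial compounds of rice. Of 14 members on the array, 6 passed the detection filter and were tested. All 6 were higher in the group mean of treated roots, with a median log2 fold change of 3.40 and 4 members below an unadjusted p of 0.05. Syn-pimara-7,15-diene synthase (Os04g0179700) differed by 3.97 ± 1.17 (SE) and a CYP99A1-like P450 (Os04g0178400), not well above background on any control array, by at least 4.42-fold. Syn-copalyl diphosphate synthase (Os04g0178300, cross-hybridising probe with its next match in the same locus) differed by 3.47 ± 1.29 and a terpenoid synthase (Os02g0571100) by 2.77 ± 1.12. Os04g0179700 and Os02g0571100 were well above background on 2 of 3 control arrays. These sizes depended on how dim signals were treated: with normexp they were 1.71 for Os04g0179700, 0.55 for Os04g0178400, 1.98 for Os04g0178300 and 1.24 for Os02g0571100. The list's median was 1.46 with normexp, 1.85 with no detection filter and 3.18 with Os04g0178400 at its bound. Os04g0178400, Os04g0179700 and Os02g0571100 passed the detection filter through the treated arrays only. That filter favours members with higher signal in treated roots, so the shared direction of the members tested is in part set by it. The camera adjusted p was 2.73e-05, and the adjusted p was 0.456 with an estimated correlation, which was 0.928 for this list. No member passed over all genes or when adjusted over the list alone, and with the replicate block 6 higher members passed when adjusted over the list alone. The pair medians were 3.14 for replicate 1 (slide 2), 5.77 for replicate 2 and 0.99 for replicate 3, because control replicate 3 lay close to the treated arrays. With background signals raised to each array's lowest signal well above background they were 2.87, 5.28 and 0.99. Without control replicate 3 the median was 4.67. The adjusted p was 4.30e-05 with the slide as a block and 3.81e-04 within slide 1, where the median was 3.47, and the list's median difference of slide 2 from slide 1 was -2.37.

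Class III peroxidases, secreted enzymes that cross-link walls and turn over hydrogen peroxide, rose as a list of 83 (61 positive, median 0.38, camera adjusted p = 0.00896), and with an estimated correlation the adjusted p was 0.682. Members below an unadjusted p of 0.05 went both ways, 4 higher and 4 lower, and 0 passed over all genes or when adjusted over the list alone. With the replicate block, 4 higher members and 1 lower passed when adjusted over the list alone. The peroxidases Os07g0677100 and Os05g0135400 had log2 fold changes of 1.62 and 1.04, and Os12g0112000 (cross-hybridising probe) had -0.69. Without a block this call was lost when some single arrays were left out. The adjusted p was 0.602 with a median of -0.02 without control replicate 1, and 0.453 with a median of 0.12 without treated replicate 2. Leaving out 1 array makes the slides unequal between the groups, so the list's slide difference enters these values. The medians of the 3 replicate pairs were 0.27, 0.26 and 0.25, and the camera adjusted p with the replicate block was 3.54e-05. The median was 0.60 without treated replicate 1 and 0.25 without treated replicate 3. With normexp it was 0.23, and with no detection filter the adjusted p was 0.0546. With the slide as a block the adjusted p was 0.00110, within slide 1 it was 0.00567 (median 0.28), and the median on slide 2 was 0.27. The median difference of slide 2 from slide 1 was -0.62 for this list. With normexp Os05g0135400 had a log2 fold change of 0.48.

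Cell wall loosening genes (120 members, 82 positive, median 0.19) did not pass the threshold without a block (adjusted p = 0.079). With the replicate block the adjusted p was 7.56e-04, with the slide as a block 0.0102 and within slide 1 0.0167 (median 0.23, against 0.17 on slide 2). With an estimated correlation the adjusted p was 0.682. Without a block the adjusted p changed when 1 array was left out: 0.929 (median -0.06) without control replicate 1 and 0.985 (0.04) without treated replicate 2. It was 1.59e-04 (0.47) without control replicate 2 and 0.00107 (0.48) without treated replicate 1. Leaving out 1 array makes the slides unequal between the groups, so the list's slide difference enters these values. The medians of the 3 replicate pairs were 0.17, 0.12 and 0.305. The adjusted p was 0.0364 with median centring, and ranged from 1.59e-04 to 0.985 over all alternatives. The list's median difference of slide 2 from slide 1 was -0.59. Examples were a polygalacturonase, an enzyme of pectin breakdown (Os05g0542800, 1.44, or 0.81 with normexp, cross-hybridising probe), a gene described as a polygalacturonase beta subunit (Os10g0409400, 0.80), and a polygalacturonase inhibitor (Os08g0510101, -1.12, or -0.22 with normexp, well above background on 2 of 3 treated arrays).

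Phenylpropanoid, lignin and flavonoid genes (74 members, median 0.10) had an adjusted p of 0.0608, of 0.0634 with the replicate block, of 0.0470 with the slide as a block, of 0.444 within slide 1 and of 0.590 with an estimated correlation. It was also below the threshold with quantile normalization (0.0484), median centring (0.0365), specific probes (0.0307), and without control replicate 2 (0.0494), control replicate 3 (0.00587) or treated replicate 3 (0.00863), and ranged from 0.00587 to 0.790 over all alternatives. The median was 0.00 without control replicate 1, 0.18 without control replicate 3, 0.03 without treated replicate 2 and 0.17 without treated replicate 3, and it was 0.04 with normexp and 0.06 within slide 1. A cinnamate 4-hydroxylase (Os02g0467600) was 2.83-fold higher (log2 fold change 0.60 with normexp) and a cinnamoyl-CoA reductase (Os01g0828100) 1.51-fold. Under the replicate block, 2 higher members of the phenylpropanoid list passed when adjusted over the list alone.

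WRKY transcription factors fell as a list. Of 69 members, 17 had a positive log2 fold change, and the median was -0.17 (camera adjusted p = 0.00220), and with an estimated correlation the adjusted p was 0.507. WRKY45 (Os05g0322900), a regulator of salicylate-dependent defence, had a log2 fold change of -1.40 ± 0.33 (SE). Its probe was marked as cross-hybridising, with the next match in the same locus. WRKY62 (Os09g0417800) had -0.73 and a WRKY25-like gene (Os08g0235800) -0.72, whereas WRKY10 (Os05g0537100) had 1.11. At an unadjusted p under 0.05, 1 member was higher and 7 lower, and 0 passed over all genes or when adjusted over the list alone. The adjusted p was 0.00110 with the slide as a block but 0.133 within slide 1, with medians of -0.19 on slide 1 and -0.14 on slide 2. Without control replicate 1 the adjusted p was 0.155 with a median of -0.12, and without control replicate 3 the median was -0.11. The list's median difference of slide 2 from slide 1 was 0.17. With normexp WRKY62 had a log2 fold change of -0.45 and Os08g0235800 of -0.47.

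Abscisic acid and dehydration genes fell as a list of 38, of which 11 had a positive log2 fold change (median -0.15, camera adjusted p = 3.54e-04). Its adjusted p was 0.456 with an estimated correlation. Of the members, 10 were lower and 0 higher at an unadjusted p under 0.05, and 0 passed over all genes or when adjusted over the list alone. With the replicate block, 1 higher and 11 lower members passed when adjusted over the list alone. Dehydrin RAB16C (Os11g0454000), a protein of water-deficit responses, had a log2 fold change of -1.10, a PM19-like membrane protein (Os05g0381400) -0.86, a late embryogenesis abundant protein (Os01g0705200) -0.75 and an aldehyde oxidase of abscisic acid synthesis (Os07g0164900) -0.45. The adjusted p was 1.38e-04 with the slide as a block and 0.00567 within slide 1 (median -0.21, against -0.31 on slide 2). Without control replicate 2, control replicate 3 or treated replicate 1 the median was -0.24, -0.27 and -0.25, and over specific probes alone it was -0.42. The list's median difference of slide 2 from slide 1 was 0.15. With normexp RAB16C had a log2 fold change of -0.60 and Os07g0164900 of -0.26.

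Ribosomal proteins rose as a list by a small and widely shared amount. Of 326 members tested, 288 had a positive log2 fold change, and the median was 0.23 (camera adjusted p = 3.89e-09). Estimating the correlation gave an adjusted p of 0.586. At an unadjusted p under 0.05, 2 were higher and 4 lower, and 0 passed over all genes or when adjusted over the list alone. The members of the smallest p were not typical of the list: a 60S L35-like gene (Os06g0732000, well above background on 1 of 3 treated arrays) had -0.77, or -0.12 with normexp, and a 50S L9-like gene (Os02g0822600) 0.45. The adjusted p was 9.14e-14 with the slide as a block and 6.52e-12 within slide 1 (median 0.21, against 0.17 on slide 2). The median was 0.09 without control replicate 1 and 0.15 without treated replicate 2, and the list's median difference of slide 2 from slide 1 was -0.37.

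Histone and cell division genes, used as markers of dividing cells in the root tip, rose as a list of 137 (99 positive, median 0.17, camera adjusted p = 0.00163). Estimating the correlation gave an adjusted p of 0.586. A histone H2A (Os08g0427700) had a log2 fold change of 0.47, a D-type cyclin (Os03g0109700) 0.59 and another D-type cyclin (Os03g0203800) -0.69, where normexp gave 0.27 and -0.36 for the cyclins. At an unadjusted p under 0.05, 4 were higher and 1 lower; 0 passed over all genes or when adjusted over the list alone, and with the replicate block 27 higher members and 1 lower passed when adjusted over the list alone. Without control replicate 1 the adjusted p was 0.263 with a median of 0.04, without treated replicate 2 it was 0.0994, and without treated replicate 1 the median was 0.30. With normexp the median was 0.11, and the list's median difference of slide 2 from slide 1 was -0.36. The adjusted p was 4.97e-06 with the slide as a block and 1.24e-04 within slide 1 (median 0.19, against 0.17 on slide 2).

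Markers of other tissues did not pass the threshold in the main fit, and some of them passed it in other settings. Shoot photosynthesis genes (55 members) had a median of 0.04 (adjusted p = 0.140), with pair medians of 0.45, 0.12 and -0.42 for replicates 1 to 3. Their adjusted p was 0.0338 with normexp and 1.00e-11 without treated replicate 3 (median 0.29), their median was -0.16 without treated replicate 1 and -0.11 within slide 1, and the adjusted p ranged up to 0.870 over all alternatives. Xylem secondary wall genes (13 members) had a median of 0.14 (0.388), with 0.32 (0.0304) without control replicate 2 and up to 0.961 elsewhere, and root hair genes (5 members) a median of -0.06 (0.593). Casparian strip and suberin genes (8 members, 2 positive) had a median of -0.30 (adjusted p = 0.104), with 0.00 on slide 2 and -0.45 within slide 1. The median was -0.48 without treated replicate 1, -0.14 with detection on all 6 arrays and -0.17 with normexp. The GPAT5-like gene of this list passed when adjusted over the list alone, and with the replicate block 2 higher xylem genes did so within theirs.

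**Figure D3:**
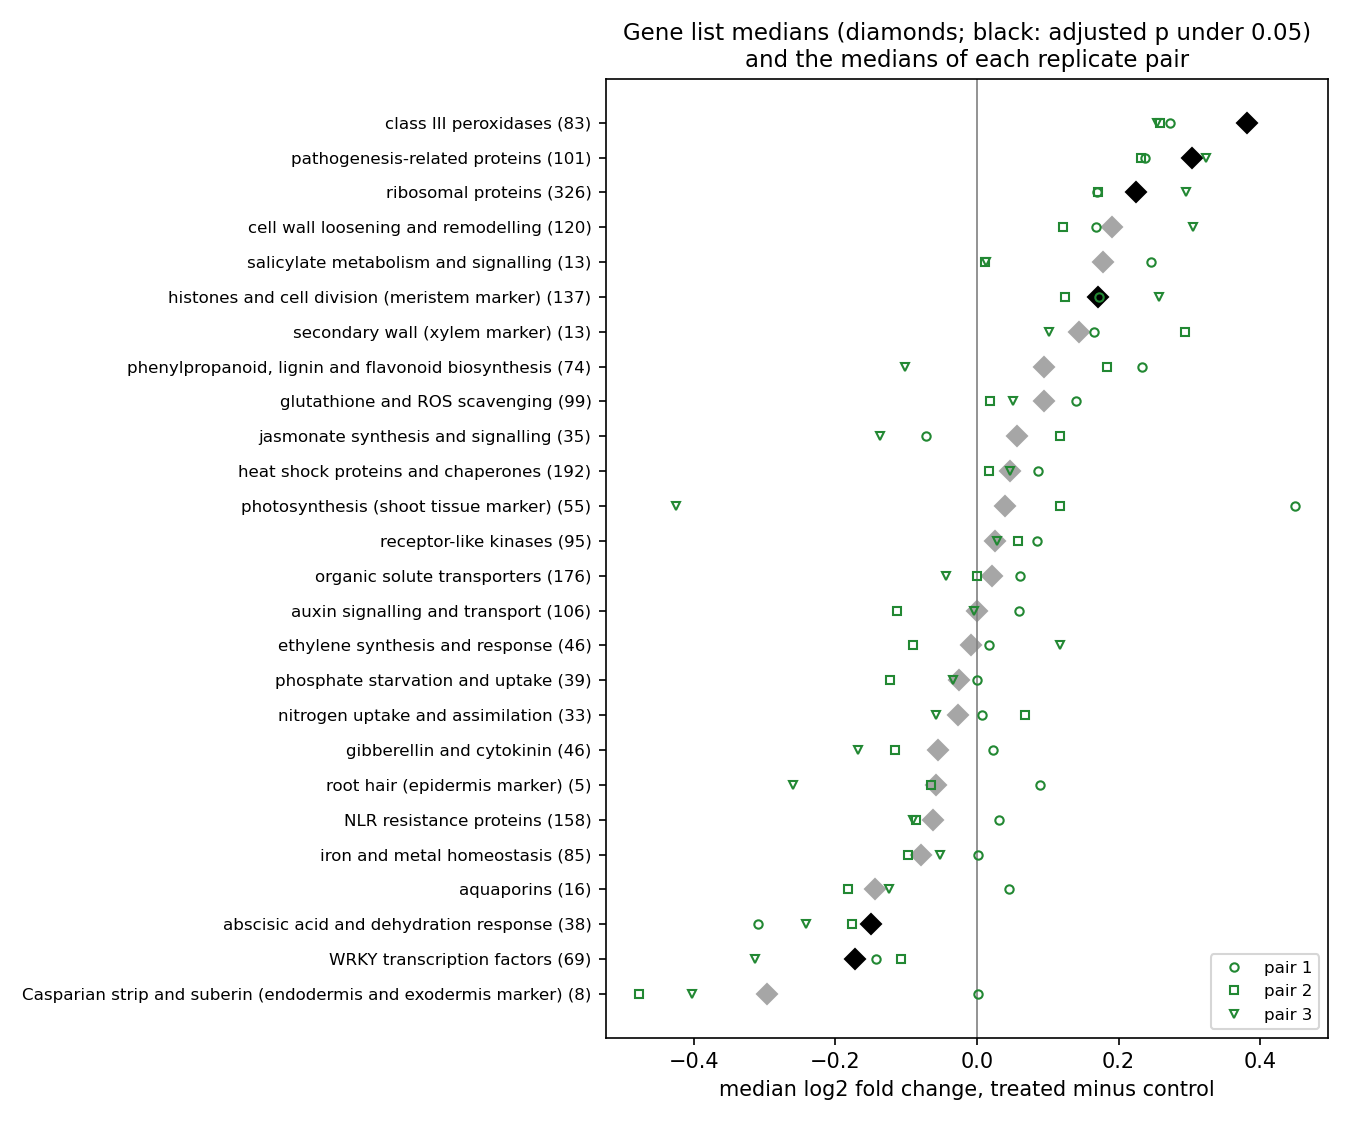
Median log2 fold change (treated minus control, horizontal) of 26 gene lists, with the number of members tested in parentheses; diamonds are medians from the group means, black where the camera adjusted p was under 0.05, and open green symbols are the medians of the 3 replicate pairs. The peroxidase median of 0.38 lies above those of all its pairs, and the photosynthesis pairs spread from -0.42 to 0.45. The diterpenoid list, with a median of 3.40, is left out for scale.

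Lists of hormones other than abscisic acid were not called. Ethylene genes (46 members) had a median of -0.01, a mean of 0.12 and an upward test (adjusted p = 0.532), and the ACC oxidase Os05g0149400 passed when adjusted over the list alone. An ethylene-responsive factor (Os03g0860100) had a log2 fold change of 1.66, or 0.87 with normexp. Salicylate genes (13 members) had a median of 0.18 (0.253), and a carboxyl methyltransferase (Os11g0256900, 0.65) and an NPR1-like gene (Os03g0667100, -0.60) passed when adjusted over the list alone. The salicylate median ranged from 0.03 without treated replicate 1 to 0.29 without treated replicate 2. Jasmonate genes (35 members) had a median of 0.06 (0.948). Auxin genes (106 members) had a median of 0.00, a mean of 0.02 and a downward test (0.948), with an auxin response factor 16-like gene (Os06g0685700) at -0.55. Gibberellin and cytokinin genes (46 members) had a median of -0.06, a mean of 0.03 and a downward test (0.530), with a gibberellin 20-oxidase (Os08g0560000) at 0.90, or 0.49 with normexp.

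Lists for signalling, nutrients and transport did not pass the threshold either. Receptor-like kinases (95 members, 13 higher and 2 lower at an unadjusted p under 0.05) had a median of 0.03 (adjusted p = 0.106), with SHR5-like receptor kinases Os08g0202300 (cross-hybridising probe) and Os08g0203201 at 0.89 and 0.86. For Os08g0202300 it was 0.47 with normexp, 0.56 with the mean of its probes and 0.24 over specific probes. NLR resistance proteins (158 members) had a median of -0.06 (0.423). Nitrogen genes (33 members) had a median of -0.03, a mean of 0.08 and an upward test (0.681), with Os02g0112600, a gene described as BCH2-like and well above background on 2 of 3 control arrays, at 2.41 (0.77 with normexp). Phosphate genes (39 members) had a median of -0.02 (0.532), and the 4 members below an unadjusted p of 0.05 were all lower, among them an SPX-domain gene (Os02g0202200, -0.97). Iron and metal genes (85 members) had a median of -0.08 (0.275), with a nicotianamine aminotransferase (Os02g0306401), of the pathway that makes iron-chelating phytosiderophores, at 0.78 (0.42 with normexp).

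Aquaporins (16 members) had a median of -0.14 (adjusted p = 0.143), with a TIP4-like gene (Os01g0232100) at -0.76 (-0.40 with normexp). Without control replicate 1 their adjusted p was 0.0135, and over all alternatives it ranged up to 0.790. Organic solute transporters (176 members) had a median of 0.02 (0.510), with a MATE efflux gene (Os04g0373400) at 1.09 and an amino acid permease (Os01g0945600) at 1.43 (0.54 with normexp). Heat shock proteins and chaperones (192 members, 14 higher and 2 lower at an unadjusted p under 0.05) had a median of 0.05 (0.079), with a DNAJ-like gene (Os06g0195800) at 1.64. Glutathione and ROS scavenging genes (99 members) had a median of 0.09 (0.0988), with a glutathione transferase (Os10g0529700) at -1.05 (-0.44 with normexp). The heat shock and glutathione lists had an adjusted p of 0.0338 with normexp, and over all alternatives they ranged up to 0.602 and 0.478.

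For the hormone, signalling, nutrient and transport lists, no member passed over all genes, and apart from the ethylene and salicylate genes named above none passed when adjusted over the list alone. Under the replicate block, the members that passed when adjusted over the list alone were, higher and lower, 2 and 0 for ethylene, 1 and 0 for jasmonate, 0 and 0 for salicylate, and 3 and 1 for gibberellin and cytokinin genes. They were 1 and 0 for receptor-like kinases, 2 and 0 for NLR proteins, 0 and 3 for phosphate genes, 3 and 5 for iron and metal genes, 0 and 1 for aquaporins, and 1 and 0 for heat shock proteins.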

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

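All alternatives with both blocks and a trend, an estimated correlation under a block, removal of the GC trend, specific probes, or lists within slide 1 were chosen after the data were seen. No named gene changed direction, but these genes were chosen from the same data by their separation or small p. None of the 111 passed in the main fit, so none could lose a call. Of their values under the alternatives, 2722 did not pass either and 22 did. Under normexp, 58 of the 111 log2 fold changes were more than 1.5 times smaller, 0 were more than 1.5 times larger and 0 turned, with a median ratio of 0.627 to the values given. The counts of genes higher and lower were 10 and 0 within slide 1, 21 and 3 with the replicate block, trend and robust variance, 37 and 16 with the slide block, trend and robust variance, and 195 and 83 at an unadjusted p under 0.05 with a 2-fold change. They were 0 and 0 under the remaining processing settings, with 976 to 3897 genes at an unadjusted p under 0.05. The unadjusted count was 3851 with the replicate block, 3314 with the slide block, 2861 within slide 1, 3897 with array weights, 4124 and 3392 with the replicate and slide blocks, trend and robust variance, and 3812 with the replicate block and GC trend removed. With 1 array left out, the counts were 0 to 1 higher, 0 to 0 lower and 922 to 2819 unadjusted.

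Lists called higher numbered 0 with an estimated correlation (also under the replicate and slide blocks) and by fry, and 8 with normexp. Lists called lower numbered 0 in those estimated-correlation and fry settings and 1 within slide 1. In the simulated data, where genes were independent, estimating the correlation also raised the adjusted p of the shifted list. It went from 2.92e-16 to 0.0216 without a block and from 6.58e-47 to 0.069 with the replicate block. A call lost with an estimated correlation can therefore reflect low power as well as correlation between genes, and these values do not tell which. With 1 array left out, 3 to 8 lists were higher and 2 to 2 lower. Adjusted p-values with an estimated correlation, by fry, and with an estimated correlation under the replicate and slide blocks, in that order, were 0.456, 0.407, 0.424 and 0.438 for pathogenesis-related proteins; 0.456, 0.407, 0.478 and 0.447 for diterpenoid genes; 0.682, 0.679, 0.424 and 0.447 for peroxidases; 0.507, 0.407, 0.447 and 0.447 for WRKY factors; 0.456, 0.407, 0.424 and 0.447 for abscisic acid genes; 0.586, 0.594, 0.471 and 0.447 for histones; and 0.586, 0.594, 0.447 and 0.447 for ribosomal proteins. The peroxidase list had an adjusted p of 0.0546 with no detection filter, and the WRKY list 0.133 within slide 1. The cause was not tested. With 1 array left out, the adjusted p ranged from 7.98e-07 to 0.00509 for pathogenesis-related proteins, from 1.67e-12 to 0.00102 for diterpenoid genes, from 5.73e-05 to 0.602 for peroxidases, from 1.59e-04 to 0.155 for WRKY factors, from 8.43e-06 to 0.0071 for abscisic acid genes, from 1.63e-06 to 0.263 for histones and from 1.33e-14 to 0.00519 for ribosomal proteins. The replicate block changed no call of a list apart from cell wall loosening. Too few diterpenoid genes were well above background on all 6 arrays for that setting to give a value. The median of all genes stayed between -0.0228 and -0.00687 under the 4 scalings.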

Other observations

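Gene groups in this part, and all tests except those of random lists and of other splits of the arrays, were chosen after the values were seen. The 5 genes tested between Os04g0178300 and Os04g0180400, the region of chromosome 4 that holds the momilactone pathway, had positive log2 fold changes, with pair medians of 3.09, 6.40 and 2.21, or 2.44, 6.06 and 2.21 with background signals raised to each array's lowest signal well above background. Os04g0178300, Os04g0178400 and Os04g0179700 belong to the fixed list, so their values repeat those given above. Outside that list are Os04g0179100 (log2 fold change 3.94) and a CYP99A2-like gene (Os04g0180400, 4.31, well above background on 2 of 3 control arrays). In the diterpenoid region of chromosome 2, 3 of 4 genes had positive values, a terpene synthase-like gene (Os02g0571800) had -0.02, and the pair medians were 1.75, 5.05 and 0.51, or 1.75, 4.58 and 0.51 with such signals raised. A P450 gene there (Os02g0570700) was well above background on all 3 treated arrays but not in control replicates 2 and 3, so control replicate 3 did not carry high signal for it. Os02g0569900 and Os02g0571100 of this region also belong to the fixed list. The 9 germin-like and oxalate oxidase genes tested between Os08g0189200 and Os08g0190100 on chromosome 8, secreted proteins of a family tied to disease resistance, had positive values (median 1.38), 5 of them at an unadjusted p under 0.05. The other 4, among them Os08g0189200 and Os08g0189300, were lower in the treated array of 1 pair, and Os08g0189400, Os08g0189850 and Os08g0189900 are on probes that cross-hybridise with other genes of the region, so they are not separate evidence. The 4 genes of the desaturase region of chromosome 7 had a median of 2.26, and Os07g0416700 there is on a probe that cross-hybridises with Os07g0416900. Of 12 genes of tryptophan biosynthesis, 10 were higher and 5 of them below an unadjusted p of 0.05, among them an anthranilate synthase beta chain (Os04g0463500, 0.93), a phosphoribosylanthranilate transferase (Os03g0126000, 0.80) and a tryptophan synthase alpha chain (Os07g0182100, 0.98). The p12 genes Os06g0688300 (at least 10.9-fold) and Os09g0472900 (log2 fold change 4.52) and the PBZ1-like genes Os12g0555000 and Os12g0555200 (2.72 and 2.79) were higher in all 3 pairs. Lipid transfer proteins went both ways, with 15 of 32 positive and a median of -0.12. None of these genes passed limma's threshold (adjusted p of 0.584 or more).

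In control replicate 3 the 6 diterpenoid genes lay at a median of 0.875 of the way from the mean of the other controls to the treated mean. They include Os04g0178400 (0.62 of the way), which was not well above background on that array. Levels near or above the treated mean were seen there for lipoxygenases (Os08g0508800 and Os08g0509100), ent-kaurene oxidases, tryptophan decarboxylase (Os08g0140500), a 1-deoxy-D-xylulose 5-phosphate synthase (Os07g0190000) and a PR-1a gene (Os07g0127500). A treated sample under the control label would put nearly all treatment-associated genes near the treated level, but of 72 other genes whose lowest treated array exceeded control replicates 1 and 2 by more than 1 log2 unit, 30 (41.7%, exact binomial 95% interval 30.2 to 53.9) lay less than 0.25 of the way and 25 more than 0.75, with a median of 0.418. Of the 40 that were well above background on all 3 control arrays, 20 (50%, interval 33.8 to 66.2) lay below 0.25, including both desaturases and the chitinase, and 7 above 0.75, which argues against a wrong label. For treated RNA mixed into this sample, 16 of 56 genes at least 4-fold higher in treated roots (28.6%, interval 17.3 to 42.2) were no higher than in the other controls. Among those well above background on all controls these were 7 of 27. Of the 56, 9 fell short of the rise such a mixture needs by more than 2 SD, too few to decide. That SD (0.98) came from control replicates 1 and 2, which lie on different slides. A mixture with these treated samples would not put control replicate 3 above all of them, as for Os07g0127500 (0.69 against -0.20 at most). The share of treated RNA implied was 0.67 at the median of the diterpenoid genes but 0.004 for the desaturase Os07g0416900. A mixture alone therefore does not account for these genes, though it may contribute. A partly induced control plant stays open, and no biological explanation was tested.

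Control replicate 1 had low signal for root-specific genes: RCc3 (Os02g0662000) differed by -4.49 from the mean of the other controls, and over 8 genes described as RCc2, RCc3, Tfm5 or root-specific the median difference from the other controls was -4.58 (SD 2.21). Treated replicate 1, on the same slide, lay -2.01 from the other treated arrays. Probe GC content and brightness predicted 1.44% of the control difference, which argues against a bias of that kind. An effect of the slide alone would need equal differences; the ratio of treated to control was 0.439, but between 0.309 and 0.575 with 1 gene left out, so slide and sample cannot be told apart for these genes. A different part or age of root in replicate 1 may be involved and stays open. Without control replicate 1 the calls of the peroxidase, histone and WRKY lists were lost (camera adjusted p = 0.602, 0.263 and 0.155). Their medians were -0.02, 0.04 and -0.12 against 0.38, 0.17 and -0.17, so that the WRKY list lost less of its size. The medians of the pathogenesis-related and ribosomal lists were 0.11 and 0.09 against 0.30 and 0.23. Leaving out control replicate 1 keeps slide 2 in the treated group only, so slide differences enter these values. Treated replicate 1 had similar offsets from its group for peroxidases (-0.58, and -0.59 in control replicate 1) and histones (-0.37 and -0.34), but not for WRKY genes (0.01 and 0.12). With the replicate block all 3 lists were called (camera adjusted p = 3.54e-05, 7.68e-07 and 7.08e-04).

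The higher ribosomal protein and histone lists moved in all 3 pairs. Of 10000 random lists of the same size and brightness, none had a median as high as the ribosomal list (0.01%, the smallest share they can give), with values from -0.05 to 0.04 against 0.23, which argues against signal level as the cause. With each array's GC trend removed the ribosomal median was 1.04 times its value, which argues against GC content as the whole cause. On the slide with the smaller median it was 0.753 times the value over both, so the difference was seen on both slides. Each slide held equal numbers of both groups, so a plain slide shift cancels and this ratio could not test it. Both lists were lower on slide 2 than on slide 1 (medians -0.37 and -0.36), as were the peroxidase (-0.62), cell wall loosening (-0.59), pathogenesis-related (-0.35) and diterpenoid (-2.37) lists. A larger share of dividing root tip tissue in treated samples may contribute as a hypothesis, was not tested, and rests on lists whose calls were lost with an estimated correlation (adjusted p = 0.586 for both).

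With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 genes past the threshold, as did all 10 (highest other 0). For genes at an unadjusted p under 0.05, 4 of the splits gave as many as the real 1436, and the highest other gave 5524. For lists called, 4 gave as many as the real 7, and the highest other gave 8. The split with 5524 genes set control replicates 1 and 3 and treated replicate 1 against the rest, which keeps slide 2 together and points to a structure of the samples along the slides and pairs. Among the 4 splits that part all 3 pairs, as the real one does, the highest other gave 390 genes, and with the replicate block 811 against 3851. For lists called, the other splits of this kind gave 3, 6 and 3 against the real 7. These 4 splits are also too few for a share under 0.05, so they do not decide whether the real grouping stands out.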
